A study of Homo sapiens with 6 samples.

How the data were processed

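RNA-seq was carried out on THP-1 cells that were induced to attach, transfected with a negative-control siRNA (si-NC, 3 libraries) or a MED23 siRNA (si-MED23, 3 libraries) and lysed 48 hours later. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit; the agent that induced attachment, the siRNA sequences and the strand setting of the counting are not given in the sources used here. The submitters' processing notes name STAR, HTSeq 0.6.0, DESeq2 and the genome build hg38. The authors deposited raw read counts per gene symbol, 1 column per library, with no normalization. The deposited count table has 19932 gene symbols and no rows of unassigned reads, so the share of reads outside genes is unknown. All 19932 symbols were found in GENCODE 29, 19907 of them as protein-coding genes, and that annotation of GRCh38 gave the coordinates, transcript lengths and GC content. In 4048 genes every library had 0 counts. Groups and replicate numbers were taken from the labels, and each column was tied to its library by the description in the labels.

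Totals were 21480047, 24835420 and 18610729 counts in si-NC replicates 1 to 3 and 20697367, 20533946 and 20280263 in si-MED23 replicates 1 to 3. Genes were kept by edgeR's filterByExpr, which left 11954 of the 15884 detected genes, and libraries were scaled by TMM with factors from 0.987 to 1.010. Differences were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, group as the only term; R 4.3.3), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. SEs and 95% intervals of log2 fold changes were derived from the quasi-likelihood F statistic and its degrees of freedom. CPM values use the TMM-scaled totals. Intervals cover the spread between libraries, not errors of mapping. The biological coefficient of variation was 6.75%, and the 95% interval of a gene's fold change reached 1.12-fold to either side in the median. Any 2 libraries differed by more than counting noise (chi-square tests of their counts over genes gave 4.17 to 14.1 per degree of freedom over 15 pairs), so none was treated as a duplicate. An exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1, so single genes were tested with the model across all genes.

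42 gene lists were fixed before the data were examined, with 1025 symbols of which 1010 were matched, 24 of them through an older symbol. The 39 lists with 3 or more tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01 and again with the estimated correlation, and with fry. Adjusted values are over the 39 lists. The rule for named genes, fixed at the same time, took MED23 and ABCA1 always, then up to 8 rising and 8 falling genes past the threshold with a mean log2 CPM of at least 2 and no overlap between groups, and up to 3 called members per list with up to 1 more in the other direction. MED23 was the only called gene, so the rule names MED23 and ABCA1, and all other genes were named after their values were seen, as the text says.

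The scripts were tested on counts simulated from these libraries' means and totals, with 200 changed genes among 11954. In the simulated si-MED23 against si-NC comparison edgeR recovered 40% of 50 genes changed 1.25-fold, 76% of those changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold, and called 11 unchanged genes.

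Alternatives set before the data were examined were DESeq2's size factors, no TMM, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a 2-fold minimum and each library left out in turn. One was added after the data were seen, in which each library's loess trend (span 0.3) of log2 CPM on transcript length and GC content was removed, alone and together with the block. Every column of the table was used. Some genes of the lists are not reported here by name.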

Results

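RNA from THP-1 cells was sequenced after knockdown of MED23. THP-1 is a human monocytic leukaemia line that becomes adherent and macrophage-like when induced, and per the labels' protocol the cells were induced to attach before transfection. MED23 encodes a subunit of Mediator, the complex that carries signals from transcription factors bound at enhancers to RNA polymerase II. There were 3 libraries from cells given a negative-control siRNA (si-NC) and 3 from cells given a MED23 siRNA (si-MED23), all harvested 48 hours after transfection. Total counts per library ran from 18610729 to 24835420, and 14207 to 14436 genes had at least 1 count in a library. The series as a whole concerns ABCA1, cholesterol efflux and macrophage inflammation, so the comparison asks what the cells' transcripts, and those genes in particular, do when MED23 is lowered. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so each p-value measures only the spread between these libraries, which may be technical.

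MED23 itself was lower in every si-MED23 library. In CPM, the read count scaled to the size of its library, its level was 44.2, 43.8 and 40.4 in si-NC and 25.7, 27.0 and 29.8 in si-MED23, with means of 42.8 ± 2.08 and 27.5 ± 2.11 CPM (SD, n = 3). The log2 fold change was -0.64 ± 0.07 (SE), which left 64.2% of the control level (95% interval of the fold, 0.574 to 0.718), with an adjusted p of 0.0154 by edgeR's quasi-likelihood test. The gene lies on the minus strand of chromosome 6, from 131573966 to 131628229 (GRCh38, GENCODE 29). ARG1, on the opposite strand, overlaps one of its ends (131573144 to 131584332) but had 10 counts over all 6 libraries, too few to be tested. MED23's adjusted p was 0.239 without si-NC replicate 1, 0.101 without si-NC replicate 2 and 0.113 without si-MED23 replicate 1, while its log2 fold change stayed between -0.70 and -0.59 whichever library was left out.

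ABCA1, the transporter that moves cholesterol from macrophages onto apolipoprotein A-I, was abundant and showed no detectable difference. It averaged 1909 ± 89.0 CPM in si-NC and 1968 ± 47.7 CPM in si-MED23 (SD, n = 3), a log2 fold change of 0.04 ± 0.05 (SE, adjusted p = 0.904, edgeR). The 95% interval of the fold ran from 0.952 to 1.12. MED23 mRNA was still at 64.2% of its control level, and these data do not give its protein. This result, and those of the uncalled lists below, therefore do not show that the genes are independent of MED23. The gene spans 104781002 to 104928237 on the minus strand of chromosome 9. Of its neighbours within 500 kb, NIPSNAP3A (log2 fold change -0.12 ± 0.11, SE), NIPSNAP3B (-0.06 ± 0.27) and SLC44A1 (-0.06 ± 0.06) could be tested, and none passed.

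**Figure D1:**
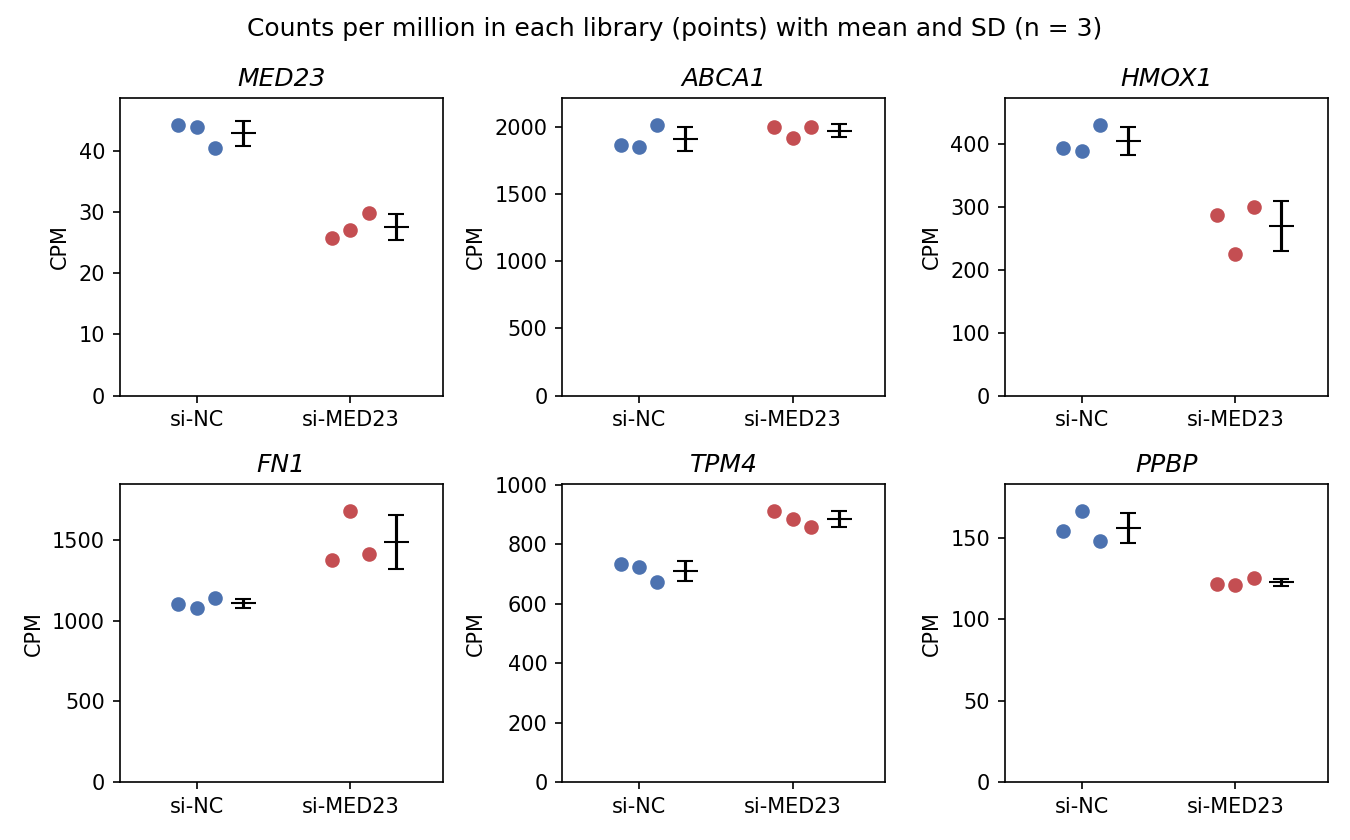
CPM (y axis, from 0) of 6 genes in the si-NC (blue) and si-MED23 (red) libraries; points are libraries and black bars the mean and SD (n = 3). MED23 falls from a mean of 42.8 to 27.5 CPM and the groups do not overlap, ABCA1 overlaps between the groups, and HMOX1, FN1, TPM4 and PPBP do not overlap but miss an adjusted p of 0.05 over all genes in edgeR.

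Across the transcriptome, MED23 was the only gene past the threshold in edgeR's test with group as the only term. Of 11954 genes tested with edgeR, 0 were higher and 1 was lower in si-MED23 at an adjusted p under 0.05, with 486 higher and 316 lower at an unadjusted p under 0.05. limma-voom also called 0 higher and 1 lower. DESeq2, whose own filter left 6466 genes to adjust over, called 10 higher and 9 lower. With the replicate number as a block, an alternative set before the data were examined, 313 genes were higher and 148 lower. The labels do not say that the numbers pair the groups, so the samples were not treated as paired. Same-numbered libraries did resemble each other across the groups, as the part on processing gives. If the numbers do pair the groups, the test by group alone may call too few genes. In 1506 genes (12.6%) all 3 values of one group lay above all 3 of the other, where chance gives 10%. The count of lower genes was 0 without si-NC replicate 1, si-NC replicate 2 or si-MED23 replicate 1. It was 2 without si-MED23 replicate 2 (MED23 and HMOX1) and 3 without si-MED23 replicate 3 (MED23, HMOX1 and S100A9).

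The genes nearest to the threshold were chosen after their values were seen, as those with an adjusted p under 0.1 in edgeR, and all were also called by DESeq2. 4 of them had lower values in si-MED23. HMOX1, haem oxygenase 1, averaged 404 ± 22.4 CPM in si-NC and 270 ± 40 CPM in si-MED23 (SD, n = 3), a log2 fold change of -0.58 ± 0.09 (SE, adjusted p = 0.0584, edgeR). NDRG2 had a log2 fold change of -0.51 ± 0.09 (adjusted p = 0.0722). MTHFD2L, a mitochondrial enzyme of folate metabolism, had -0.41 ± 0.06 (adjusted p = 0.0584), and PPBP, a CXC chemokine best known from platelets, had -0.35 ± 0.06 (adjusted p = 0.0655). The other 4 had higher values. FN1, the matrix protein fibronectin, averaged 1107 ± 30.5 CPM in si-NC and 1488 ± 166 CPM in si-MED23, a log2 fold change of 0.43 ± 0.07 (adjusted p = 0.0722). PCNX3 had a log2 fold change of 0.37 ± 0.05 (adjusted p = 0.0584). GANAB, the catalytic subunit of glucosidase II in the endoplasmic reticulum, had 0.32 ± 0.05 (adjusted p = 0.0584), and TPM4, an actin-binding tropomyosin, had 0.32 ± 0.05 (adjusted p = 0.0722).

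DESeq2 added 10 more genes, again named because of that call. Higher in si-MED23 were ANXA6 (log2 fold change 0.34 in edgeR), GNLY (0.31), CUX1 (0.26), EPB41L3 (0.26), STX12 (0.26) and HERC1 (0.25). Lower were GPAT3, an acyltransferase of triglyceride synthesis (-0.44), S100A9, a myeloid calcium-binding protein (-0.43), BIRC3, an inhibitor of apoptosis (-0.29), and TGFB3 (-0.28). DESeq2's adjusted p ran from 0.000699 for S100A9 to 0.0488 for CUX1, EPB41L3 and GPAT3. edgeR's adjusted p for the same genes ran from 0.108 for S100A9 to 0.486 for GPAT3.

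The lists below were fixed from the cell line, the siRNA target and the series' subject before any value was seen. MED23 is in none of them, and no member of any list was called by edgeR over all genes tested. The members named as examples are those with the smallest p in their list or those passing when adjusted over the list alone, so they were chosen after their values were seen. 7 of the 39 lists with at least 3 tested members were called by camera, which compares a list's genes with all other genes, at its preset inter-gene correlation of 0.01. None was called with the correlation estimated from these libraries, where the adjusted p was 0.596 for each of the 7. At the preset correlation 4 were called without si-NC replicate 1 and 3 without si-MED23 replicate 2, and 5 to 9 with another library left out.

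Genes of cholesterol handling showed no detectable shift as groups. Among 21 tested LXR targets and efflux genes, which include ABCA1, the median log2 fold change was 0.01 and camera's adjusted p was 0.280. ABCG1, the other main efflux transporter, averaged 39.1 ± 4.55 CPM in si-NC and 44.1 ± 4.46 CPM in si-MED23 (SD, n = 3), a log2 fold change of 0.17 ± 0.09 (SE, adjusted p = 0.777, edgeR). ABCA7 had a log2 fold change of 0.55 ± 0.20 at a mean of 3.09 CPM in si-NC (adjusted p = 0.646). The 28 genes of SREBP2-driven cholesterol synthesis and uptake had a median of -0.04 (camera adjusted p = 0.280), with MSMO1 at -0.24 ± 0.07 and IDI1 at -0.16 ± 0.07. The 28 genes of lipid uptake, storage and lysosomal cholesterol had a median of -0.03 (camera adjusted p = 0.895). Members lay on both sides of 0, with the fatty acid chaperone FABP5 at -0.24 ± 0.07 and the receptor LRP1 at 0.34 ± 0.11. Medians were -0.01 for the 16 genes of fatty acid synthesis (camera adjusted p = 0.392) and -0.05 for the 14 of fatty acid oxidation (0.362). Adjusted over the list alone, 0 genes passed in each of these 5 lists.

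Inflammatory genes likewise showed no detectable shift as groups, in cells where some of them were highly expressed. CXCL8 and IL1B together took 5.40% to 6.27% of all counts in a library. The 24 inflammatory cytokines and chemokines tested had a median log2 fold change of 0.03 (camera adjusted p = 0.280). In that list TNFSF15 had 0.28 ± 0.08 (SE), IL23A 0.38 ± 0.13 and IL6 0.16 ± 0.06, with adjusted p values of 0.486, 0.641 and 0.705 over all genes (edgeR). For the 27 NF-kB response genes the median was -0.03 (camera adjusted p = 0.714). BIRC3 was the 1 gene of that list to pass when adjusted over the list alone, and PTGS2, the inducible cyclooxygenase, lay at 0.33 ± 0.10. The 22 Toll-like receptor and inflammasome genes had a median of 0.02 (camera adjusted p = 0.479), with NLRP3 at 0.16 ± 0.06 and NLRC4 at -0.47 ± 0.17. Medians were 0.00 for 34 immediate early genes (camera adjusted p = 0.895) and 0.05 for 20 alternative activation markers (0.256). CYR61 and FN1 respectively passed in those 2 lists when adjusted over the list alone.

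Interferon-stimulated genes differed more between libraries of one group than between the groups. The 36 tested members had a median log2 fold change of 0.05 (camera adjusted p = 0.996). IFIT1, an interferon-induced RNA-binding protein, was at 33.2, 26.5 and 16.6 CPM in the si-NC libraries and at 47.7, 23.3 and 11.4 CPM in the si-MED23 libraries. MX1 was at 85.0, 67.8 and 49.8 CPM in si-NC and at 121, 61.3 and 38.8 CPM in si-MED23. Leaving out 1 library decided the outcome for this list. Without si-MED23 replicate 1 it was called lower in si-MED23 (camera adjusted p = 0.000150), and without si-MED23 replicate 3 it was called higher (0.000171). Antigen presentation genes had medians of 0.12 (class I, 7 genes, camera adjusted p = 0.236) and 0.10 (class II, 8 genes, 0.280). Without si-MED23 replicate 3 both were called higher (0.0288 and 0.0220), as class II was without si-NC replicate 2 (0.0248). NLRC5, an activator of class I genes, passed when adjusted over the list alone (log2 fold change 0.22 ± 0.06, SE).

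NRF2 targets and other genes of oxidative stress defence formed one of 3 lists called lower. Of 21 tested members 17 had a negative log2 fold change and the median was -0.09 (camera adjusted p = 0.000378; adjusted p = 0.596 with an estimated correlation). Adjusted over the list alone, 6 passed, all lower. They were HMOX1, the transcription factor NRF2's own gene NFE2L2 (log2 fold change -0.20 ± 0.05, SE), glutathione reductase GSR (-0.35 ± 0.10), the glutathione synthesis enzyme subunit GCLC (-0.26 ± 0.08), TALDO1 (-0.19 ± 0.07) and thioredoxin TXN (-0.19 ± 0.07). Camera's adjusted p was 0.110 without si-MED23 replicate 2 and between 7.44e-05 and 0.0169 without any other library. The median deviation of si-MED23 replicate 2 from the mean of all 6 was -0.25, against 0.00 and 0.01 in the other 2 si-MED23 libraries and 0.05 to 0.12 in si-NC.

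Histone genes had the lowest median of the lists, -0.22 over 10 tested members of which 9 were negative (camera adjusted p = 0.000378; adjusted p = 0.596 with an estimated correlation). Replication-dependent histone mRNAs usually lack a poly(A) tail, and the list was included as a sign of how RNA was selected. HIST1H2AC (21.1 CPM in si-NC, log2 fold change -0.37 ± 0.10, SE) and HIST2H2BE (93.8 CPM, -0.22 ± 0.07) passed when adjusted over the list alone. Genes of one histone type resemble each other closely, so reads may be split uncertainly between them. Camera's adjusted p stayed between 0.000171 and 0.0163 whichever library was left out. The proliferation lists beside it had medians of -0.08 for 37 DNA replication genes (camera adjusted p = 0.280) and -0.04 for 24 mitotic genes (0.469).

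The 15 heat shock genes were also called lower, with a median of -0.05 and 13 negative members (camera adjusted p = 0.0365; adjusted p = 0.596 with an estimated correlation). The co-chaperone DNAJA1 lay at -0.19 ± 0.06 (SE) and HSPA8 at -0.09 ± 0.05, and 0 passed when adjusted over the list alone. With 1 library left out, the call stood only without si-MED23 replicate 1. It was lost without si-NC replicate 1 (0.0524), si-NC replicate 2 (0.0912), si-NC replicate 3 (0.140), si-MED23 replicate 2 (0.176) and si-MED23 replicate 3 (0.140), and also with trends of transcript length and GC content removed (0.0813), an alternative added after the data were seen.

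Cytoskeletal genes driven by serum response factor (SRF) formed the first of 4 lists called higher. Among 22 tested members 17 were positive and the median was 0.10 (camera adjusted p = 0.000378; adjusted p = 0.596 with an estimated correlation). Adjusted over the list alone, 3 passed, all higher. They included TPM4 and the focal-adhesion protein VCL (log2 fold change 0.16 ± 0.05, SE). Camera's adjusted p was between 0.000671 and 0.0177 whichever library was left out.

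Matrix and adhesion genes were called higher with a smaller median of 0.06 over 34 members, 26 of them positive (camera adjusted p = 0.0365; adjusted p = 0.596 with an estimated correlation). FN1 was the 1 gene to pass when adjusted over the list alone, and COL4A2 lay at 0.38 ± 0.11 (SE) and THBS1 at 0.37 ± 0.12. The call was lost without si-NC replicate 1 (0.174), si-NC replicate 2 (0.131), si-MED23 replicate 2 (0.110) and si-MED23 replicate 3 (0.137), and with the length and GC trends removed (0.0813).

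Hypoxia and glycolysis genes were called higher, with a median of 0.08 over 30 members and 23 positive (camera adjusted p = 0.00383; adjusted p = 0.596 with an estimated correlation). ERO1A lay at 0.17 ± 0.06 (SE), the phosphofructokinase PFKP at 0.20 ± 0.07 and the glucose transporter SLC2A1 at 0.16 ± 0.06, and 0 members passed when adjusted over the list alone. The call was lost without si-NC replicate 3 (0.0629) and without si-MED23 replicate 2 (0.0818).

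All 13 mRNAs encoded by mitochondrial DNA had positive log2 fold changes, with a median of 0.12 (camera adjusted p = 0.00282; adjusted p = 0.596 with an estimated correlation). MT-ND1 lay at 0.16 ± 0.06 (SE) and MT-ND5 at 0.14 ± 0.06, and 0 members passed when adjusted over the list alone. Their share of all counts was 1.36% to 1.47% in si-NC and 1.43% to 1.51% in si-MED23. The call was lost without si-NC replicate 1 (0.0524), si-NC replicate 2 (0.0579) and si-MED23 replicate 3 (0.0604). The nuclear-encoded respiratory chain genes had a median of -0.01 over 32 members (camera adjusted p = 0.714).

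**Figure D2:**
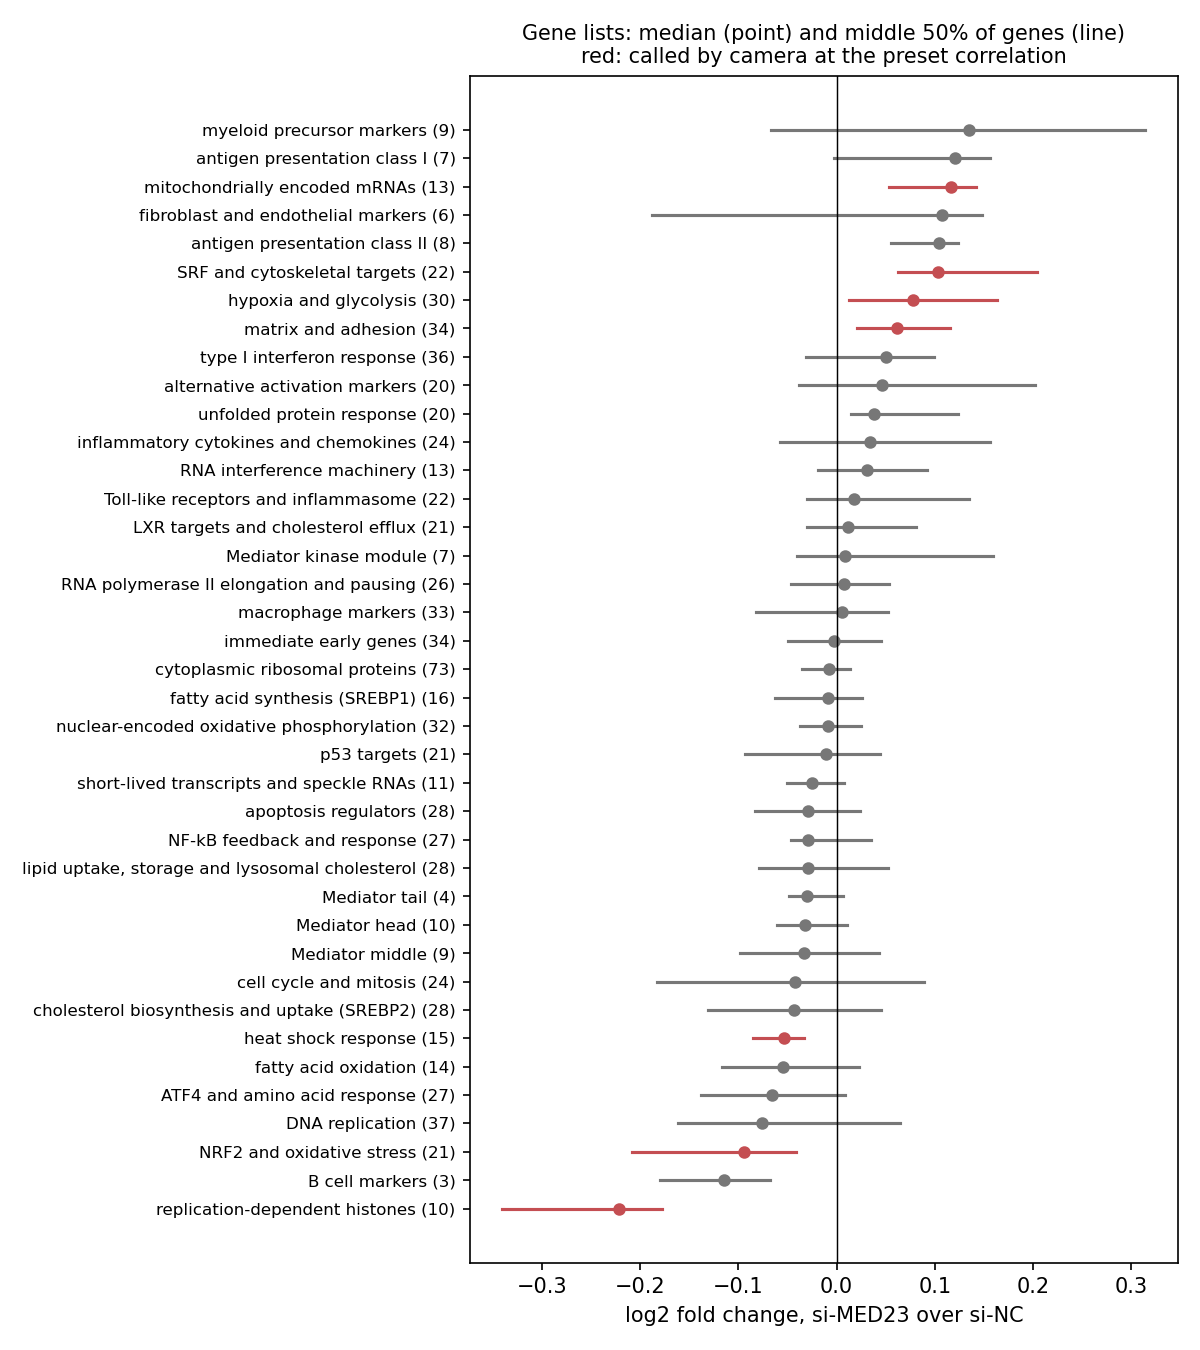
Median log2 fold change of si-MED23 over si-NC (x axis) for the 39 gene lists, with the number of tested genes in brackets; lines span the middle 50% of each list's genes and red marks the 7 lists called by camera at the preset correlation. Medians run from -0.22 for histones to 0.13 for myeloid precursor markers.

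The lists of other Mediator subunits were not called by camera. Median log2 fold changes were -0.03 for 10 head subunits (camera adjusted p = 0.749), -0.03 for 9 middle subunits (0.412) and -0.03 for the 4 tail subunits other than MED23 (0.895). The 7 genes of the kinase module had a median of 0.01 (0.412). In the kinase module MED13L passed when adjusted over the list alone (log2 fold change 0.19 ± 0.05, SE) and MED12 lay at 0.16 ± 0.06. By fry, which asks whether a list's own genes change in either direction, the kinase module had an adjusted p of 0.0136 and the SRF list 0.00286, and no other list passed. In fry's test of a shift in one direction no list passed, with an adjusted p of 0.257 for the SRF list and 0.408 for the kinase module. Factors of RNA polymerase II pausing and elongation had a median of 0.01 over 26 genes (camera adjusted p = 0.895), and 13 genes of the RNA interference machinery had 0.03 (0.412).

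Stress and death programmes other than those above were not called in the planned test of all 6 libraries. Medians were 0.04 for 20 genes of the unfolded protein response (camera adjusted p = 0.154), -0.07 for 27 ATF4 and amino acid response genes (0.202), -0.01 for 21 p53 targets (0.449) and -0.03 for 28 apoptosis regulators (0.198). The unfolded protein response was called higher (0.0324) with trends of transcript length and GC content removed, an alternative added after the data were seen. It was also called higher (0.0440) with the replicate number as a block, an alternative set before the data were examined. The ATF4 list was called lower without si-MED23 replicate 3 (0.0477). ATF4 itself lay at -0.17 ± 0.06 (SE). The 73 cytoplasmic ribosomal protein genes had a median of -0.01 (camera adjusted p = 0.714).

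Marker lists of macrophages and of other cell types were not called in the planned test of all 6 libraries. The 33 macrophage markers had a median of 0.01, although their mean was -0.03 and camera's direction was down (camera adjusted p = 0.895). The integrin subunit ITGB2 averaged 3703 ± 135 CPM in si-NC and 4003 ± 249 CPM in si-MED23 (SD, n = 3), a log2 fold change of 0.11 ± 0.06 (SE, adjusted p = 0.777, edgeR). The 9 tested myeloid precursor markers had a median of 0.13 (camera adjusted p = 0.157) and were called higher without si-MED23 replicate 3 (0.0458) and, over 8 genes, with a filter of at least 1 CPM in 3 libraries (0.0301). Markers of other cell types were mostly under 1 CPM, at 10 of 12 T cell, 7 of 10 B cell, 11 of 13 epithelial, 7 of 12 fibroblast and endothelial, and 13 of 14 erythroid and megakaryocyte genes. The exceptions with the highest levels were PECAM1 (627 CPM over the 6 libraries), FCRLA (144 CPM) and PPBP (139 CPM). The 3 tested B cell markers had a median of -0.12 (camera adjusted p = 0.392) and the 6 fibroblast and endothelial markers 0.11 (0.469). As a sign of RNA quality, 11 short-lived transcripts and speckle RNAs had a median of -0.03 (0.412).

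**Figure D3:**
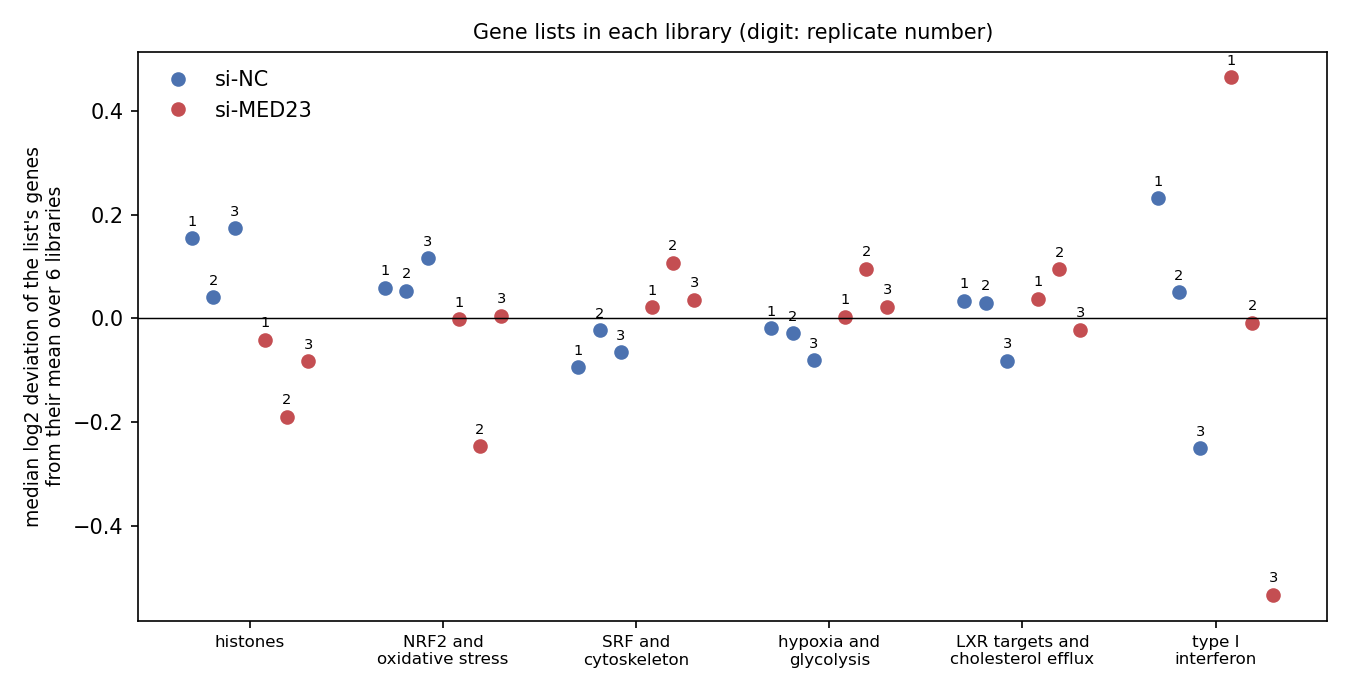
Median log2 deviation of a list's genes from their mean over the 6 libraries (y axis), for 6 lists (x axis) in the si-NC (blue) and si-MED23 (red) libraries; digits are replicate numbers. Histone, NRF2, SRF and hypoxia medians separate the groups, NRF2 is lowest in si-MED23 replicate 2 (-0.25), and the interferon list runs from 0.47 to -0.53 within si-MED23.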

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

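The tests with transcript length and GC content were chosen only after the data were seen. MED23's log2 fold change stayed negative, and its adjusted p under 0.05, in each alternative run for it on all 6 libraries, from 4.68e-08 (DESeq2) to 0.0233. With 1 library left out it ran from -0.70 to -0.59, and it missed the threshold without si-NC replicate 1 (-0.62, adjusted p = 0.239), si-NC replicate 2 (-0.62, 0.101) or si-MED23 replicate 1 (-0.59, 0.113). It passed without si-NC replicate 3 (0.0262), si-MED23 replicate 2 (0.0415) or si-MED23 replicate 3 (0.00589). The call thus depended on which library was left out, not only on having fewer libraries. ABCA1 stayed positive and uncalled in the alternatives run for it, from 0.00 to 0.08.

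Counts of called genes, 0 higher and 1 lower as reported, were 1 and 2 with library size only (no TMM), 6 and 8 with no low-count filter, 10 and 9 in DESeq2, and 4 and 4 with the length and GC trend removed. With a 2-fold minimum 0 were lower. Leaving out 1 library gave 0 higher and 0 to 3 lower. Lists called, 7 as reported, were 0 with an estimated correlation and 3 to 9 with 1 library left out, lowest without si-MED23 replicate 2. In other settings 6 to 8 were called, the eighth being myeloid precursor markers (0.0301) with a filter of 1 CPM in 3 libraries. The cause of these shifts was not tested.

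The groups share replicate numbers, and with the number as a block 313 genes were higher and 148 lower, or 176 and 131 with the length and GC trend removed as well. In the simulated counts, which held no effect of the number, the fit with the block called 20 unchanged genes, against 11 by group alone. Part of the block's calls may therefore be false. With the block alone MED23 was at -0.64 and ABCA1 at 0.04, and 6 lists were called. The heat shock (0.0591) and matrix (0.0587) lists were lost and the unfolded protein response (0.0440) gained, as with the trend alone removed (0.0813, 0.0813 and 0.0324). Over all 11954 tested genes the deviations of same-numbered libraries correlated at 0.05, 0.21 and 0.22 for numbers 1, 2 and 3, and over 9450 genes with a mean log2 CPM of at least 2 at 0.18, 0.46 and 0.48. Every library correlated best with its own number. That is a hint from the data, not from the labels, so the samples were not treated as paired.

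Of 128 genes named in the text or in its tables, MED23 and ABCA1 left out, none changed direction while past a threshold. None of them was called as reported, so a reversal required a new call with the opposite sign, and its absence says little. What did change was the calls. Of the 128, 65 passed with the replicate number as a block, 18 in DESeq2 and 12 with no low-count filter. Depth limits the low genes. In simulated data of this depth and spread edgeR found 76% of genes changed 1.5-fold and 40% of those changed least. Far more genes were changed there than were called in the real comparison, which makes the adjusted threshold easier to pass. These shares therefore tend to overstate what was detectable here, and small changes can be missed.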

Other observations

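The tests of the chromosome 4 pair, of 1 library, of length and GC trends and of the median without HMOX1 for the NRF2 list, of total counts and replicate number for the interferon list, and of other splits for the count of genes and for single lists were chosen only after the result was seen.

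A few groups outside the main comparison describe the cells themselves. CXCL8, which alone took 2.79% to 3.41% of all counts in a library, stood at 32877 CPM in si-NC and 30506 CPM in si-MED23. Of its neighbours on chromosome 4, CXCL1 averaged 2488 and 2470 CPM, CXCL3 1152 and 1088 CPM, CXCL5 1070 and 1001 CPM, and CXCL2 710 and 691 CPM. None of these 5 chemokine genes passed (adjusted p from 0.815 to 0.980, edgeR).

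PPBP and MTHFD2L, 2 of the 9 genes with an adjusted p under 0.1, lie in that same stretch of chromosome 4, 126 kb apart (PPBP at 73987038 to 73988197 and MTHFD2L at 74114174 to 74303099, GRCh38). Both were lower in si-MED23, at log2 fold changes of -0.35 and -0.41. Random sets of 9 tested genes held a pair as close in 1.24% of 10000 draws, but the pair was noticed first and the draw built on its distance, so chance placement stays open. A candidate explanation is that the whole neighbourhood was lower, and the other 10 tested genes within 500 kb, CXCL8 and EREG among them, had a median log2 fold change of -0.0892 (standard error 0.0318), 8 of them negative, with EPGN beside MTHFD2L at -0.60 ± 0.34 (SE) and under 2 CPM. The median lies 8.16 standard errors above PPBP's change, but that error comes from resampling the 10 genes and leaves out the spread between libraries. The pair was also picked for its large changes, so this distance cannot weigh a fall of the whole stretch. CXCL5, CXCL3 and CXCL2 lie between PPBP and MTHFD2L. Their log2 fold changes were smaller than the pair's, at -0.10 ± 0.09, -0.08 ± 0.08 and -0.04 ± 0.09 (SE). The median is also within 1 standard error of -0.1, the bound first set, so a smaller shared shift stays open.

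Whether the lower NRF2 list rests on 1 library stays open. Camera's adjusted p was 0.000378 with all 6 libraries and 0.110 without si-MED23 replicate 2, where 14 of the 21 members were lower and the median went from -0.10 to -0.05 on the log2 CPM scale, and the other 2 si-MED23 libraries (0.00 and 0.01) still lay below the 3 si-NC libraries (0.05 to 0.12). Camera's unadjusted p was under 0.05 in all 10 splits of the libraries (0.000125 to 0.0462 in the 9 others, 2.30e-05 by label), so its p without that library, without HMOX1 (0.00206, the test planned) or without the length and GC trends (0.00175) decides nothing. Over the other 20 members the median was -0.0924 and 16 were negative. Of these members 5 passed when adjusted over the list alone (edgeR), so lower values in these libraries were not confined to HMOX1. The members move together between libraries (estimated correlation 0.620), and these tests were not run over the other splits. The 5 are therefore not separate support for a fall of the list with MED23. The median's standard error of 0.0431 comes from resampling the genes. It leaves out the spread between libraries, so it cannot weigh HMOX1 alone as an explanation. With the trends removed the list's median was -0.0969, which argues against the trends as the whole cause. What remains open is that si-MED23 replicate 2 differed in its redox state or handling for reasons apart from MED23, and an effect of MED23 itself, which these 3 libraries cannot separate from it.

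Interferon-stimulated genes varied 2-fold among the si-MED23 libraries. The list's median deviation was 0.47, -0.01 and -0.53 in si-MED23 replicates 1, 2 and 3 and 0.23, 0.05 and -0.25 in the si-NC replicates. Library depth cannot account for it, because the totals of the si-MED23 libraries lie within 2.06% of each other, and thinning all libraries to one total, the test first planned, left a gap of 1.00 log2. The full gap of 1.00 log2 between the highest and lowest si-MED23 library was 0.981 after the length and GC trends were removed. In si-NC 31 and in si-MED23 32 of the 36 members were highest in replicate 1 and lowest in replicate 3, where a random order gives 6, but as a set the 3 libraries would come in one given order with a probability of 0.167, so something shared by the number, an innate response to transfection and a difference in cell state all stay open.

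Whether chance can be excluded for the counts of calls is beyond this design, since 6 libraries make 10 splits of 3 against 3. The split by label called 1 gene and the highest other split 23, and 3 of the 10 splits called at least as many genes as the labels. For gene lists the split by label called 7 and the highest other split 10, and 3 of the 10 splits called at least as many. Camera's unadjusted p was smallest by label for the NRF2, histone and SRF lists, while another split gave a smaller one for the mitochondrial (5.22e-06 against 0.000289 by label), hypoxia (0.000299 against 0.000491), matrix (0.000397 against 0.00655) and heat shock (0.00115 against 0.00605) lists. The split with 23 genes, singled out because its count was the highest, set si-NC replicates 1 and 3 and si-MED23 replicate 3 against the other 3 libraries. It put the replicate 3 libraries of both groups against the replicate 2 libraries of both. Over the 9450 genes with a mean log2 CPM of at least 2, deviations of the replicate 2 libraries of both groups correlated at 0.46. Those of the replicate 3 libraries correlated at 0.48 and those of the replicate 1 libraries at 0.18. Replicate 2 of one group against replicate 3 of the other gave -0.44 and -0.37. These values go with a structure shared by the replicate number, whose source was not tested. Genes called in this split included the matrix metalloproteinases MMP1, MMP3, MMP8 and MMP10, the growth factor CSF2 and the lipid receptor TREM2. MMP1, for example, was at 924, 624 and 1112 CPM in si-NC replicates 1 to 3 and at 841, 615 and 1243 CPM in si-MED23 replicates 1 to 3. In each group it was lowest in replicate 2 and highest in replicate 3. Genes called in this split tend to have si-NC replicate 2 and si-MED23 replicate 3 at opposite ends. Part of this order was therefore fixed by how the gene was picked.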
